A study of Mus musculus with 6 samples.

How the data were processed

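Per the file headers and the authors' processing notes, the arrays were 1-colour Agilent mouse arrays read with Feature Extraction 10.7.3.1. The deposited scanner tables hold a processed signal, a background-corrected fluorescence intensity in arbitrary units that is not on a log scale. The deposited series table holds log2 values shifted so that each array's 75th percentile lies near 0. Its array medians ran from -3.95 to -3.61, and its values correlated with the log2 scanner signal at 1. It was used only as an alternative.

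The labels describe male ob/ob mice given propolis extract or a dilute DMSO and ethanol vehicle. Cells came from mesenteric fat by collagenase digestion and red cell lysis, and 0.1 µg of RNA was labelled. The labels call the samples biological replicates and do not state how many mice each holds, so p-values here measure spread between these samples. Slides were numbered in the order they appear in the headers.

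The processed signal was turned to log2, spots flagged as non-uniform were left out, replicate spots were averaged, and each array's 75th percentile was subtracted. A probe entered if it stood well above background on at least 3 of the 6 arrays, as 34786 of 55681 probes did. Of these, 4 lacked a value on an array and were dropped. The brightest entering probe stood for its gene, giving 25777 genes and transcripts, 15772 with a symbol. Symbols came from RefSeq accessions matched to a reference table of the mouse assembly GRCm38.p6, used for names only, while the array design was made on mm9. No symbol was found for 28446 probes, and no coordinates are given.

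Groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes without a block, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The prior had 2.36 degrees of freedom. With 3 arrays against 3, an exact permutation p cannot be below 0.1. Where a gene stood above background on no array of the dimmer group, its fold is a lower bound under the main processing. The bound compares the brighter group's mean with the dimmer group's mean of, on each array, the higher of the gene's own signal and the lowest signal of any probe well above background. Named genes are the 12 with the largest differences in each direction among those with symbols that passed without overlap, up to 4 genes of lowest p in each called list and in the M1, M2, pan-macrophage and fatty acid synthesis lists, and the mutated gene Lep. Of the genes this rule selects, 1 is not reported here.

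Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists, and beside it with camera at an estimated correlation and with fry. The lists were eosinophils, pan-macrophage, classical (M1), alternative (M2), lipid-associated macrophage and large peritoneal macrophage genes, neutrophils, dendritic cells and antigen presentation, type 2 cytokines and innate lymphoid type 2 genes, T cells, regulatory T cells, B cells, plasma cells, natural killer and cytotoxic genes, mast cells and basophils, adipose progenitors, extracellular matrix and fibrosis, adipocyte genes, fatty acid and triglyceride synthesis, fatty acid oxidation, thermogenic genes, cholesterol synthesis, liver X receptor and cholesterol export genes, NRF2 antioxidant genes, aryl hydrocarbon receptor and xenobiotic genes, interferon-stimulated genes, cell cycle, blood endothelium, lymphatic and lymph node stroma, pericytes and smooth muscle, mesothelium, pancreatic acinar cells, intestinal epithelium, erythroid cells, enteric nerve and glia, dissociation and immediate early genes, unfolded protein response, insulin signalling and glucose uptake, and hypoxia and glycolysis. Of their 485 genes, 468 had a probe. The comparison, the lists, the naming rule and all alternatives but 3 were chosen before the data were examined.

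Alternatives covered background correction, scaling, the filter, flags, the probe rule, the variance model, array weights, the series table, blocks for slide and replicate number, slide 1 alone, each array left out, other list tests and other thresholds. Background correction by normexp was planned on mean signals, which the scanner tables do not hold, so median signals were used. No spot was saturated, so leaving out saturated probes could not move any result and was not run. The 3 alternatives added later left out vehicle 2 and vehicle 3 together, left out population outlier spots, and used only genes with symbols as background for camera.

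In 20 simulations of the same size with 200 changed genes, 8.96% of 2-fold, 53.6% of 4-fold and 86.9% of 16-fold changes were recovered, and 4.52% of calls were unchanged genes. A shifted list was called in 18 of 20 simulations, and 3 lists were called falsely in all simulations together. The simulated genes varied independently of each other, so these list counts do not hold for lists of correlated genes. In the data the estimated correlation was 0.82 for T cell genes and 0.88 for B cell genes.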

Results

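Gene expression was measured in the stromal vascular fraction of mesenteric fat, the mixture of non-adipocyte cells that collagenase digestion releases, from male ob/ob mice. These mice carry a mutation in the leptin gene and become obese. The mice had received intraperitoneal Brazilian propolis extract, a bee product, at 100 mg/kg 2 times a week for 12 weeks, or vehicle, and 3 samples of each group were hybridised to 1-colour arrays. Values are log2 intensities relative to each array's 75th percentile, and every ± is an SD with n = 3. The 75th percentile of intensity ranged from 525.8 in vehicle 2 to 858.9 in propolis 1, and 61.1% to 66.7% of the 59305 spots per array stood well above background. Vehicle 1, vehicle 2, propolis 1 and propolis 2 shared slide 1 and scan 1, and vehicle 3 and propolis 3 shared slide 2 and scan 2. Across genes, arrays correlated with each other at 0.940 to 0.989, and arrays of one group were on average 0.00684 closer than arrays of different groups. That value was 0.00340 without propolis 1, 0.00338 without propolis 2 and 0.0104 without vehicle 1. The first principal component held 39.5% of the variance and set vehicle 3 apart from the other arrays, and the second held 26.9% and separated vehicle 1 and vehicle 2 from the rest.

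Mean levels of markers of neighbouring organs were high in single arrays. In vehicle 2 the pancreatic acinar genes averaged 4.38, against -3.51 to -2.61 in the other arrays, with the amylase gene Amy2a5 at 7.21 and the carboxypeptidase gene Cpb1 at 4.96. In vehicle 3 the intestinal epithelial genes averaged 4.82, against -3.44 to -0.40 elsewhere, with the fatty acid binding protein gene Fabp2 at 8.33. The acinar gene Clps was at 3.93 in vehicle 2 and 1.44 in vehicle 3, against -1.71 to -1.33 in the other arrays. B cell genes averaged 1.56 in vehicle 2 and -0.30 in vehicle 1, and -2.80 to -1.71 in the other 4 arrays.

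The comparison of propolis with vehicle asked which genes in these cells differ after the treatment. The genes with the largest differences were mostly higher after propolis. The fibrillar collagen gene Col24a1 had a fitted rise of 199.5-fold, an uncertain size because vehicle 1 did not measure it well above background. Calca, which encodes calcitonin gene-related peptide, was 72.4-fold higher, going from -4.59 ± 0.14 to 1.59 ± 0.46. Retnla, which encodes a protein secreted by alternatively activated macrophages, was 6.83-fold lower, from 7.15 ± 0.11 to 4.38 ± 0.56. Mmp12, the macrophage elastase, was 5.90-fold lower and Itgax, the integrin CD11c of dendritic cells and fat macrophages, 4.53-fold lower. Among gene groups, lipid-associated macrophage, cholesterol synthesis and adipocyte genes stood lower, and matrix and mesothelial genes stood higher, by a test with a preset correlation between genes. With an estimated correlation 0 of these lists were called, at an adjusted p = 0.487 for the lipid-associated, cholesterol and matrix lists and 0.602 for the adipocyte and mesothelial lists.

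Of 25777 genes and unnamed transcripts tested with limma, 215 changed at an adjusted p under 0.05, of which 186 rose and 29 fell, all by at least 2-fold. The wider set, at least 2-fold with an unadjusted limma p under 0.05, was less one-sided, with 813 higher and 472 lower. Symbols were attached to 148 that rose and 20 that fell. Groups did not overlap for any of the 215, and for 4478 of all genes tested, or 17.4%, where chance gives 10%. With slide as a block 313 genes passed, 256 higher and 57 lower, and 198 of the 215 were among them. Within slide 1 alone, 2 arrays against 2, limma called 0 genes and 5856 had an unadjusted p under 0.05. Slide 2 holds 1 array of each group, so it allows no test. Leaving out vehicle 1, 2 or 3 gave 53, 11 and 41 genes, of which 40, 11 and 33 were among the 215. Leaving out propolis 1, 2 or 3 gave 77, 11 and 94, of which 66, 10 and 70 were among them. Without vehicle 2 and vehicle 3 together, 1 array against 3, limma called 0 genes, with 1362 at an unadjusted p under 0.05.

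Of the 12 named genes with the largest fitted rises, 6 have a measured fold and 6 only a lower bound, so their order by true fold is not known. Among the 6 measured, Col24a1 and Lama1 were not well above background on vehicle 1. Col24a1 (probe A_51_P408430) went from -4.60 ± 0.86 to 3.04 ± 0.46 (adjusted p = 0.00652). Lama1, a laminin chain of basement membranes, had a fitted rise of 175.6-fold (adjusted p = 0.0172). Both were well above background on 2 of the 3 vehicle arrays. On vehicle 1 they lay at -5.58 and -6.01, under the lowest signal well above background there, -5.33. Their exact folds are therefore uncertain. Calca rose with an adjusted p of 0.00554, and its close relative Calcb was at least 56.2-fold higher (adjusted p = 0.00975). The transcripts of the 2 genes are similar, and whether their probes share signal was not tested. The tendon transcription factor gene Scx was 29.9-fold higher (adjusted p = 0.0178), and Tnmd, which encodes the tendon protein tenomodulin, was at least 11.4-fold higher (adjusted p = 0.0317). The adhesion genes Cdh3, encoding P-cadherin, and Ncam1 were 31.9-fold (adjusted p = 0.00975) and 28.7-fold (adjusted p = 0.0128) higher.

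The homeobox gene Gbx2 was at least 11.3-fold higher (adjusted p = 0.00652), Prss35 at least 12.0-fold (adjusted p = 0.0153) and Tmem132d at least 5.40-fold (adjusted p = 0.00652). Saa2, an acute-phase serum amyloid gene with near-identical relatives, was at least 8.86-fold higher (adjusted p = 0.00975). Vehicle arrays did not measure Calcb, Tnmd, Gbx2, Prss35, Saa2 or Tmem132d well above background, so their folds are lower bounds, under the main processing only. In other settings the fitted log2 difference was as low as 3.325 for Calcb, 1.837 for Tnmd and 1.571 for Gbx2. For Prss35, Saa2 and Tmem132d it was as low as 1.593, 1.415 and 1.042. Each of these is smaller than the gene's bound. For the 6 with a measured fold, Col24a1, Lama1, Calca, Cdh3, Scx and Ncam1, differences ranged from 4.70 to 8.15 on slide 1 and from 4.44 to 6.62 on slide 2. Groups that do not overlap force the same direction on both slides, and over all tested genes the differences on the slides correlated at 0.122. All 12 had a slide-blocked adjusted p of 0.0371 or less. Col24a1, Calca and Gbx2 passed whichever single array was left out, and the highest adjusted p of the other 9 was 0.142, for Tnmd. Of the 215 genes, 33 were not well above background on any vehicle array and 5 on any propolis array.

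Of the 12 named genes with the largest fitted falls, 11 have a measured fold, from 2.95 for Qpct to 6.83 for Retnla. Retnla differed by -2.77 (adjusted p = 0.0197), Mmp12 by -2.56 (adjusted p = 0.0307) and Itgax by -2.18 (adjusted p = 0.0405). Insm1, a zinc-finger transcription factor gene of neuroendocrine cells, differed by -2.51 (adjusted p = 0.00975) and Ptchd1 by -2.37 (adjusted p = 0.0262). Zranb3, which encodes a DNA helicase, differed by -2.13 (adjusted p = 0.0405), and Afp, the alpha-fetoprotein gene, by -2.07 (adjusted p = 0.0471). The lipase family gene Lipn was at least 2.67-fold lower under the main processing (adjusted p = 0.0205), because no propolis array measured it well above background. In other settings the fitted difference of Lipn was as small as -0.4449. Slc9a4, a sodium-proton exchanger gene, and Tnip3 each had an adjusted p of 0.0361, with differences of -1.87 and -1.68. Mreg differed by -1.62 (adjusted p = 0.0476) and Qpct, encoding glutaminyl cyclase, by -1.56 (adjusted p = 0.0460). Differences of the 11 measured genes ran from -3.15 to -1.69 on slide 1 and from -2.31 to -1.32 on slide 2, and with slide as a block Afp (adjusted p = 0.0569) and Qpct (adjusted p = 0.0558) did not pass. None of the 12 passed whichever single array was left out, with a highest adjusted p of 0.201 for Mreg. Lep itself differed by -1.68 without passing (adjusted p = 0.248), at -1.37 ± 0.75 in vehicle and -3.05 ± 0.72 in propolis.

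**Figure D1:**
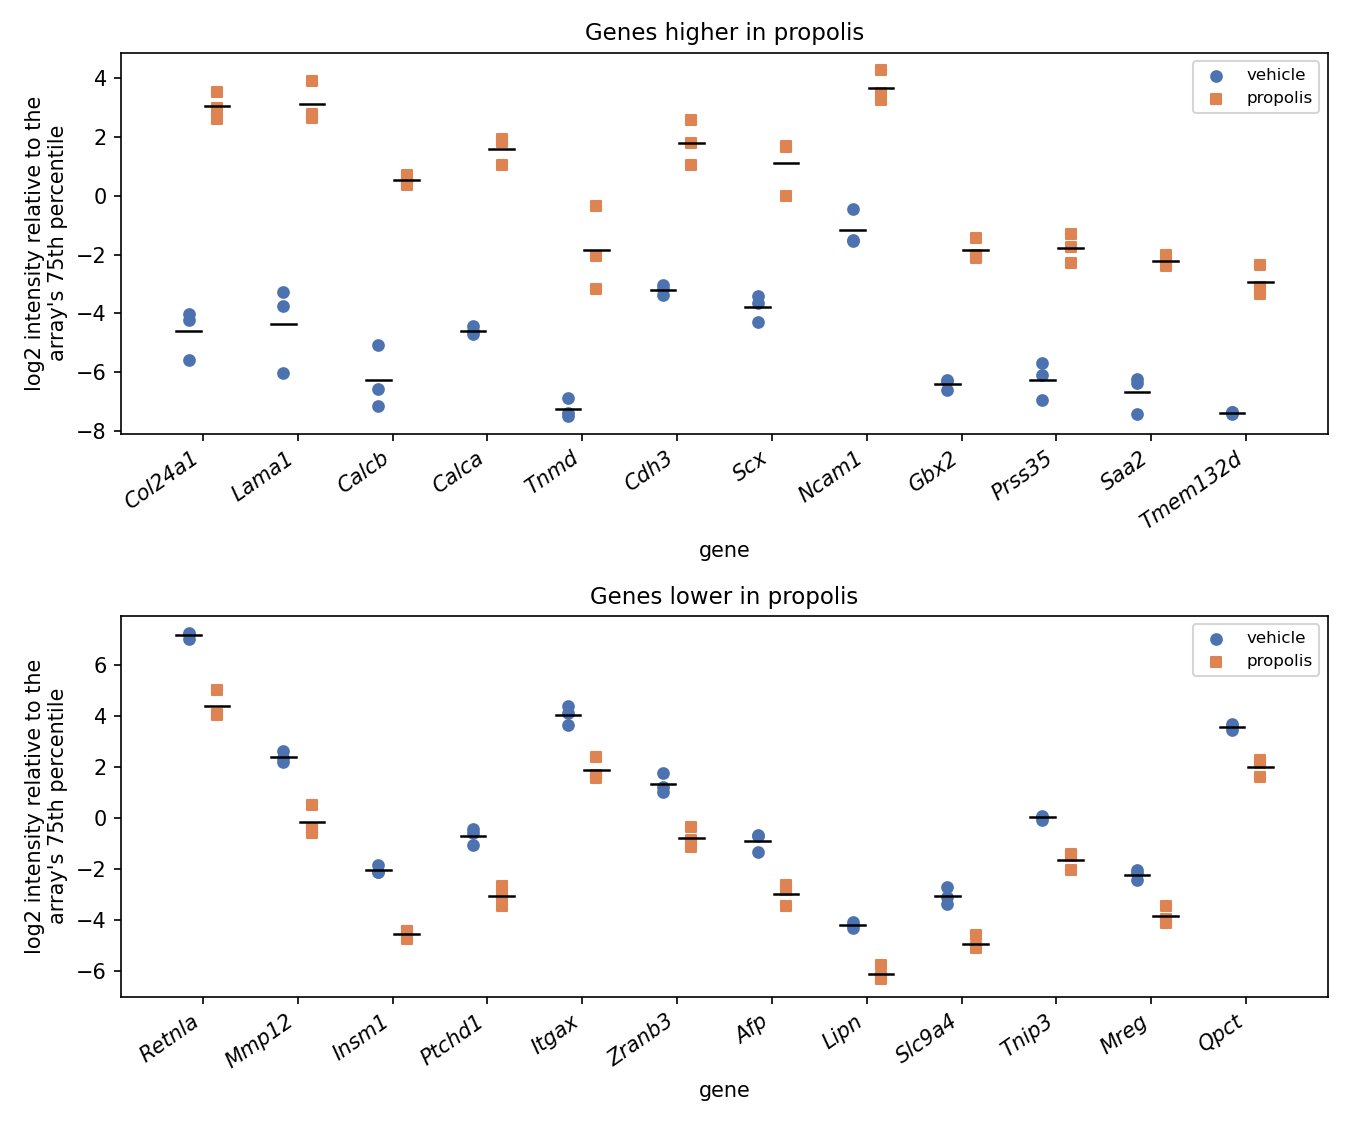
Log2 intensity relative to the array's 75th percentile of the 24 named genes with the largest fitted differences, with a point for each of the 3 vehicle and 3 propolis arrays. Propolis and vehicle points do not overlap for any of these genes, and Retnla lay at 7.15 in vehicle and 4.38 in propolis on average.

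Genes of lipid-associated macrophages, the lipid-handling macrophages of obese fat, stood lower. Of 13 measured, 12 had lower means, and Mmp12, Lgals3 and Itgax fell. Lgals3, encoding galectin-3, went from 7.88 ± 0.12 to 6.73 ± 0.04 (adjusted p = 0.0405), and did not pass with any 1 array left out (adjusted p from 0.0718 to 0.206). Itgax did not pass in any of these settings either, and Mmp12 passed in 1 of 6. The proton pump subunit gene Atp6v0d2 differed by -1.95 (adjusted p = 0.0519). Adjusted over the list alone, 8 fell and 1 rose, Spp1, which encodes osteopontin and differed by 1.56. Fabp5, Trem2, Cd9 and Plin2 passed by neither adjustment, with differences of -0.61, -0.49, -0.26 and -0.63. For Trem2 and Plin2 the groups overlapped. The list's median difference was -0.83 (camera adjusted p = 4.10e-08, and adjusted p = 0.487 with an estimated correlation), with a slide-blocked adjusted p of 1.08e-06 and medians of -0.90 on slide 1 and -0.99 on slide 2. Pan-macrophage genes had a median of -0.09 (adjusted p = 0.933), and of 11 measured, limma called 0 and 1 had an unadjusted p under 0.05. Among these, the Fc receptor gene Fcgr1 differed by 0.84, Lyz2 by -0.60, Cd14 by 0.50 and Mertk by 0.37. On slide 1 their median was -0.11 and on slide 2 0.07 (slide-blocked adjusted p = 0.947), and it ran from -0.15 to 0.10 with 1 array left out, being above 0 without vehicle 1, propolis 1 or propolis 3.

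Classical (M1) inflammatory genes had a median of -0.17 (adjusted p = 0.868), -0.24 on slide 1 and 0.19 on slide 2 (slide-blocked adjusted p = 0.910). Leaving out vehicle 1 took it to -0.08 and leaving out propolis 2 turned it to 0.09. Adjusted over all genes limma called 0 of 13, with 5 at an unadjusted p under 0.05, and adjusted over the list alone 2 rose. The chemokine gene Ccl3 differed by 0.97 (adjusted p = 0.0906), Ptgs2, encoding cyclooxygenase 2, by 2.38 (adjusted p = 0.146), Ccl4 by 0.87 and Il6 by 1.84. Most of the list went the other way, with 5 genes higher and 8 lower, among the latter Cd40 at -0.76 and Nos2 at -0.62. Alternative (M2) genes moved in both directions, with Ccl8, a chemokine gene, 6.00-fold higher (5.08 ± 0.51 to 7.67 ± 0.42, adjusted p = 0.0344) and Retnla lower. Ccl8 did not pass with any 1 array left out (adjusted p from 0.0526 to 0.143). The M2 list had a median of 0.26 (adjusted p = 0.954), 0.09 on slide 1 and 0.00461 on slide 2 (slide-blocked adjusted p = 0.910), and adjusted over the list alone 1 rose and 1 fell. Without vehicle 2 its median was 0.16, and without propolis 1, 2 or 3 it was 0.05, 0.08 and 0.03. Folr2 differed by -0.49 and Pdcd1lg2 by -0.60, short of the threshold. Among large peritoneal macrophage genes, Gata6, a transcription factor gene, rose 4.42-fold (adjusted p = 0.0307). It was chosen after its values were seen, and not refitted with an array left out. Which cells its transcript came from was not tested. The list of 11 had a median of 0.69 (adjusted p = 0.145), 0.50 on slide 1 and 0.71 on slide 2. Of the 6 arrays left out in turn, the list was called without vehicle 1 alone (1.06, adjusted p = 0.0237). Its median was 0.47 without vehicle 2 or vehicle 3 and 0.34 without propolis 1. Of the 11 genes of this list, 7 had higher and 4 had lower means. Adjusted over the list alone, 3 rose, Gata6, Garnl3 and Tgfb2. By the same adjustment 2 fell, Timd4, which differed by -1.91, and Icam2, by -1.135.

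Extracellular matrix and fibrosis genes stood higher, 15 of 19. Over all genes limma called 0, with 10 at an unadjusted p under 0.05, and 7 rose adjusted over the list alone. Col5a1, a fibrillar collagen gene, went from 4.09 ± 0.04 to 5.35 ± 0.39 (adjusted p = 0.0853), and the gelatinase gene Mmp2 differed by 1.34 (adjusted p = 0.100). Lox, encoding the collagen cross-linking enzyme lysyl oxidase, differed by 1.92 and the proteoglycan gene Lum by 0.81. The list's median was 0.62 (camera adjusted p = 4.26e-06, and adjusted p = 0.487 with an estimated correlation), with a slide-blocked adjusted p of 5.02e-06 and medians of 0.59 and 1.00 on slides 1 and 2. Mesothelial genes, marking the cells that line the peritoneum, had a median of 1.46, and 9 of 10 had higher means. The list's mean ran from -0.57 to 1.53 in vehicle and from 1.46 to 2.35 in propolis, so the groups overlapped. The transcription factor genes Bnc1 (7.29-fold, adjusted p = 0.0299) and Wt1 (3.94-fold, adjusted p = 0.0320) rose, and 5 rose adjusted over the list alone. With 1 array left out Bnc1 passed in 1 of 6 settings (adjusted p from 0.0448 to 0.127, passing without vehicle 1) and Wt1 in 0 (from 0.0575 to 0.144). Upk1b differed by 2.31 (adjusted p = 0.0932) and Msln, the mesothelin gene, by 1.91 (adjusted p = 0.218). The mesothelial list had a camera adjusted p of 3.81e-05, and adjusted p = 0.602 with an estimated correlation, with a slide-blocked adjusted p of 0.000457 and medians of 1.63 and 2.27 on the slides. Its median was 0.89 with array weights (camera adjusted p = 0.00907) and 0.99 without vehicle 2.

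All 18 cholesterol synthesis genes had lower means in propolis. The sterol transporter gene Stard4 went from 0.99 ± 0.19 to -0.20 ± 0.16 (adjusted p = 0.0542), and Msmo1, Sqle and Idi1, enzymes of the pathway, differed by -0.81, -1.01 and -0.92. Over all genes limma called 0, with 7 at an unadjusted p under 0.05, and adjusted over the list alone 4 fell. The median was -0.54 (camera adjusted p = 4.10e-08, and adjusted p = 0.487 with an estimated correlation), with a slide-blocked adjusted p of 1.36e-08 and medians of -0.40 and -0.79 on slides 1 and 2. All 13 adipocyte genes were lower too, with Lpl, the lipoprotein lipase gene, going from 6.90 ± 0.21 to 5.59 ± 0.35 (adjusted p = 0.0796). Cidec, a lipid droplet gene, differed by -1.41 and Fabp4 by -0.61. Over all genes limma called 0 of these, with 6 at an unadjusted p under 0.05, and 1 fell adjusted over the list alone. The mean of the adipocyte list was 1.65 on vehicle 1 and 1.71 on propolis 3, so the groups overlapped. Which cells of this fraction the adipocyte transcripts came from was not tested. The adipocyte median was -0.71 (camera adjusted p = 1.43e-05, and adjusted p = 0.602 with an estimated correlation), with a slide-blocked adjusted p of 8.14e-06 and medians of -0.72 and -0.69 on the slides. Without vehicle 1 the adipocyte median was -1.14, and without vehicle 2 and vehicle 3 together it was -0.44 (adjusted p = 0.0552). Fatty acid and triglyceride synthesis genes had a median of -0.19 (adjusted p = 0.933), -0.13 on slide 1 and -0.22 on slide 2 (slide-blocked adjusted p = 0.910), and turned to 0.18 without vehicle 3 and was -0.05 without propolis 1, -0.11 without propolis 2 and -0.13 without vehicle 2. Adjusted over the list alone 2 of 13 rose, the malic enzyme gene Me1 at 1.15 (adjusted p = 0.0809 over all genes) and the citrate lyase gene Acly at 0.65 (adjusted p = 0.187), and Elovl6 and Dgat2 differed by -0.52 and -1.33.

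Mast cell and basophil genes stood lower, 7 of 8. The protease genes Cpa3 and Mcpt4 differed by -1.10 and -1.29 and fell adjusted over the list alone, Cma1 differed by -1.05 and Fcer1a by -0.65, and over all genes limma called 0, with 5 at an unadjusted p under 0.05. The median was -0.82 (camera adjusted p = 0.000516, and adjusted p = 0.602 with an estimated correlation), with a slide-blocked adjusted p of 0.000220 and medians of -1.0 on slide 1 and -0.44 on slide 2. Dendritic cell and antigen presentation genes were lower in 11 of 12, with the class II gene H2-Aa at -0.90, Batf3 at -0.88, Clec9a at -0.55 and Cd209a the exception at 0.82. Their median was -0.58 (camera adjusted p = 0.000523, and adjusted p = 0.714 with an estimated correlation), -0.84 on slide 1 and -0.06 on slide 2 (slide-blocked adjusted p = 0.000457), and -0.91 without propolis 3. All 8 eosinophil genes had lower means. Among them were the eotaxin receptor gene Ccr3 at -1.14, Siglecf at -1.03 and Il5ra at -0.78. Ear2, one of a family of near-identical genes, differed by -0.40. Prg2, Ear6 and Ear1 barely moved, at -0.11 each (SE 0.37, 0.37 and 0.40). The eosinophil median was -0.39 (camera adjusted p = 0.0490, and adjusted p = 0.602 with an estimated correlation), -0.63 on slide 1 and 0.04 on slide 2 (slide-blocked adjusted p = 0.0444). Leaving out vehicle 2 (-0.32, adjusted p = 0.144) or propolis 2 (-0.10, adjusted p = 0.195) ended that call, and the median was -0.65 without propolis 3. It also ended with quantile scaling (0.0642), a percentile over detected probes (0.0723), the mean of a gene's probes (0.0574), each probe on its own (0.0584) and without vehicle 2 and vehicle 3 together (0.100). Interferon-stimulated genes stood higher, 9 of 12, with Oasl2 at 1.14, Oas1a at 0.80, Isg15 at 0.76 and Ifit3 at 0.62. Their median was 0.50 (camera adjusted p = 0.0437, and adjusted p = 0.775 with an estimated correlation), 0.47 on slide 1 and 0.57 on slide 2. The interferon call ended with slide as a block (adjusted p = 0.0572) and without vehicle 2 (0.144), vehicle 3 (0.0837), propolis 1 (0.124) or propolis 3 (0.241). It ended as well on slide 1 alone (0.301), with array weights (0.833), with named genes as background (0.120) and without vehicle 2 and vehicle 3 together (0.439). In the dendritic, eosinophil and interferon lists limma called 0 genes over all genes or adjusted over the list alone, with 3, 2 and 4 at an unadjusted p under 0.05.

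The medians of the B cell and T cell lists were lower in propolis on slide 1 and not on slide 2, where Il7r, Ccr7 and Cd4 were still lower. All 10 B cell genes had lower means, with Cr2 at -3.24, Ms4a1, the CD20 gene, at -2.87 and Fcer2a at -2.30. The B cell median was -1.92 (camera adjusted p = 7.77e-05, and adjusted p = 0.723 with an estimated correlation), -3.23 on slide 1 and 0.25 on slide 2 (slide-blocked adjusted p = 0.000457). Without vehicle 2 it was -1.15. All 15 T cell genes had lower means, with the chemokine receptor gene Ccr7 at -2.20, Cd8b1 at -1.31, the interleukin 7 receptor gene Il7r at -1.22 and Cd4 at -0.41. Their median was -0.87 (camera adjusted p = 4.74e-05, and adjusted p = 0.739 with an estimated correlation), -1.57 on slide 1 and 0.56 on slide 2 (slide-blocked adjusted p = 0.000457), and -0.47 without vehicle 2 and -1.37 without vehicle 3. Over all genes limma called 0 genes of either list, with 3 B cell and 2 T cell genes at an unadjusted p under 0.05. Adjusted over the list alone 1 T cell gene fell and 0 B cell genes did.

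The 11 blood endothelial genes were lower, with Egfl7 at -0.89, the junction genes Cdh5 and Cldn5 at -0.80 and -1.02, and Esam at -0.50. Their median was -0.80 (camera adjusted p = 0.000385, and adjusted p = 0.723 with an estimated correlation), -0.99 on slide 1 and -0.52 on slide 2 (slide-blocked adjusted p = 7.39e-05), and -0.42 without propolis 2. Cell cycle genes were lower in 13 of 15, with the replication genes Mcm5 and Mcm2 at -0.79 and -0.41, Top2a at -0.88 and Rrm2 at -0.74. Their median was -0.74 (camera adjusted p = 0.00624, and adjusted p = 0.775 with an estimated correlation), -0.52 on slide 1 and -1.02 on slide 2 (slide-blocked adjusted p = 0.0240). Propolis 2 stood apart with a mean of 0.92 over the cell cycle genes, against -0.79 in propolis 3 and a lower mean still in propolis 1. The cell cycle median was -1.34 without propolis 2, and the call ended without propolis 1 (-0.26, adjusted p = 0.110) and without propolis 3 (-0.53, adjusted p = 0.254), on slide 1 alone (0.301) and with array weights (0.663). The 6 pancreatic acinar genes had a median of -2.67 (camera adjusted p = 0.0473, and adjusted p = 0.775 with an estimated correlation), -3.31 on slide 1 and -0.07 on slide 2, with Clps at -3.00, Ctrb1 at -2.34 and Ctrl at -1.76. Cpb1 was well above background on 2 of 3 vehicle arrays and 1 of 3 propolis arrays, so its difference is not given. Without vehicle 2, the array with the high acinar genes, their median was -0.01 (adjusted p = 0.800), and with slide as a block the call ended (adjusted p = 0.107). It also ended without propolis 1 (0.0741), propolis 2 (0.0966) or propolis 3 (0.241), on slide 1 alone (0.175), with array weights (0.813), a percentile over detected probes (0.101) or the mean of a gene's probes (0.0508), and without vehicle 2 and vehicle 3 together (0.953). In the endothelial, cell cycle and acinar lists limma called 0 genes over all genes or adjusted over the list alone, with 2, 1 and 1 at an unadjusted p under 0.05.

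**Figure D2:**
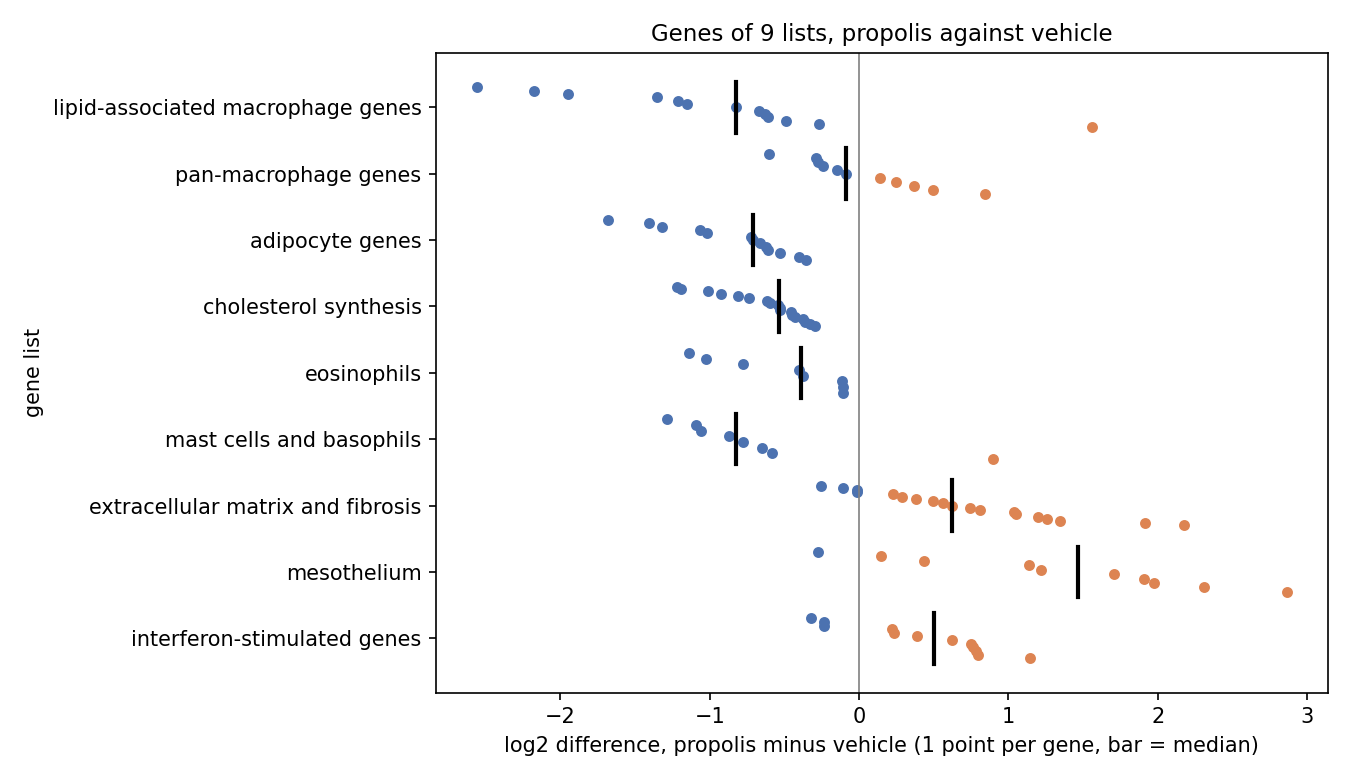
Log2 difference, propolis minus vehicle, of each gene in 9 lists, with a point per gene and a bar at the median. Mesothelial genes had the highest median shown, 1.46, and lipid-associated macrophage genes the lowest, -0.83.

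The other lists were not called by camera on all 6 arrays. Intestinal epithelial genes, high in vehicle 3, had a median of -1.76 (adjusted p = 0.212), 1.89 on slide 1 and -8.64 on slide 2. Thermogenic genes had a median of -0.54 (adjusted p = 0.156), lymphatic and lymph node stroma genes -0.78 (0.445) and neutrophil genes 0.60 (0.492). Unfolded protein response genes had 0.36 (0.107), dissociation and immediate early genes 0.20 (0.200), and aryl hydrocarbon receptor and xenobiotic genes 0.29 (0.227). NRF2 antioxidant genes had a median of -0.12 (0.417), natural killer and cytotoxic genes 0.11 (0.596), fatty acid oxidation genes 0.06 (0.635) and enteric nerve and glia genes -0.09 (0.635). Regulatory T cell genes had -0.0075 (0.710), insulin signalling and glucose uptake genes -0.07 (0.825) and erythroid genes -0.03 (0.831). Pericyte and smooth muscle genes had a median of 0.04, hypoxia and glycolysis genes 0.00507 and plasma cell genes -0.11, each with an adjusted p of 0.933. Adipose progenitor genes had -0.16 (0.933), although Clec11a, a member, rose by 1.22 (adjusted p = 0.0409; chosen after its values were seen, and not refitted with an array left out). Genes of the liver X receptor and cholesterol export had 0.08 (0.936), and type 2 cytokine and innate lymphoid genes 0.15 (0.954). Adjusted over the list alone, 3 xenobiotic genes rose and 1 fell, 1 type 2 gene rose and 1 fell, 1 unfolded protein response gene fell and 1 progenitor gene rose.

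Some of these lists were called with 1 array left out. Without vehicle 1 intestinal genes (-3.04, adjusted p = 0.00332), thermogenic genes (-0.73, 0.00475), dissociation genes (0.33, 0.0260) and erythroid genes (0.71, 0.0382) were called. Without vehicle 2 intestinal genes (-2.96, 0.0182) were, and without vehicle 3 fatty acid oxidation genes (0.20, 0.0352). Without propolis 1 NRF2 genes (-0.22, 0.0110) were called, and without propolis 2 unfolded protein response genes (0.56, 0.00565) and dissociation genes (0.40, 0.00551). Medians of most of these lists depended on single arrays. Over the 6 settings neutrophil genes ran from 0.02 to 0.95, lymphatic genes from -1.06 to -0.17, plasma cell genes from -0.49 to 0.55 and regulatory T cell genes from -0.33 to 0.12. Thermogenic genes ran from -0.85 to -0.31, intestinal genes from -3.04 to 0.79, erythroid genes from -0.51 to 0.71 and pericyte genes from -0.33 to 0.20. Natural killer genes ran from -0.05 to 0.37, type 2 genes from -0.14 to 0.16, NRF2 genes from -0.22 to 0.15 and unfolded protein response genes from 0.12 to 0.56. Dissociation genes ran from 0.07 to 0.40, xenobiotic genes from 0.00157 to 0.35, fatty acid oxidation genes from -0.00109 to 0.20 and liver X receptor genes from -0.02 to 0.15. Enteric nerve genes ran from -0.21 to 0.02, insulin signalling genes from -0.21 to -0.02, hypoxia genes from -0.09 to 0.11 and adipose progenitor genes from -0.25 to -0.10.

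**Figure D3:**
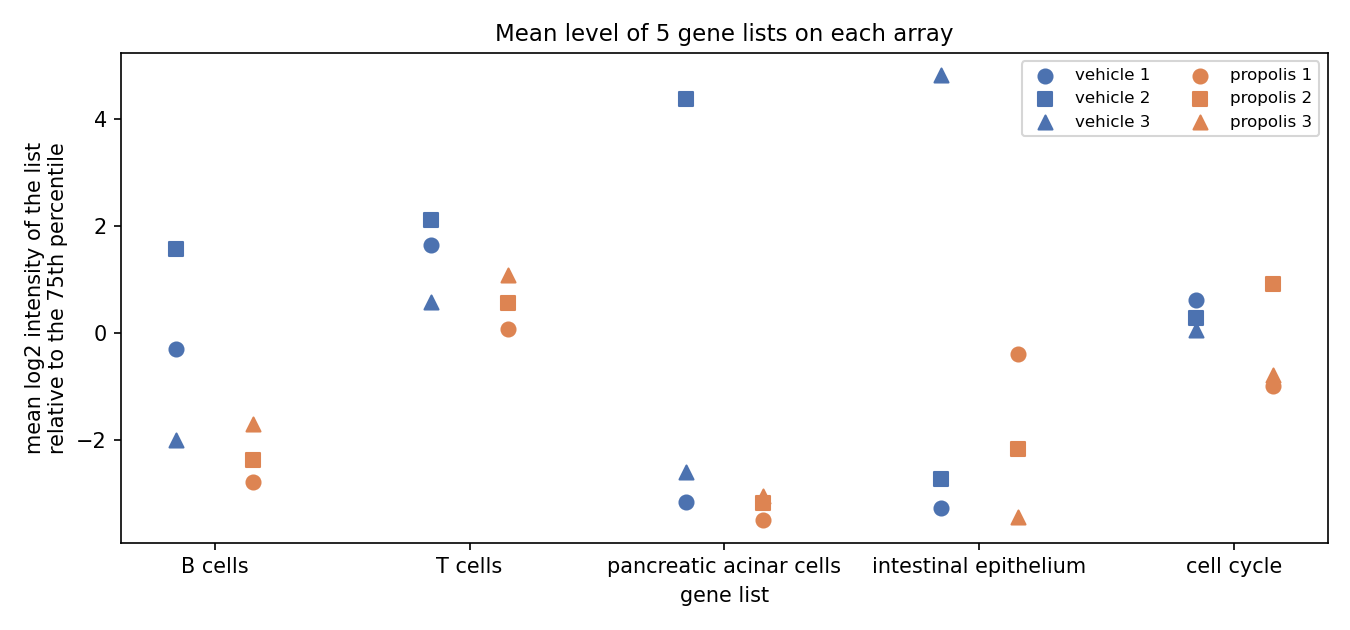
Mean log2 intensity of 5 gene lists on each of the 6 arrays, relative to the array's 75th percentile. The mean of the acinar genes reached 4.38 in vehicle 2 alone, and that of the intestinal genes 4.82 in vehicle 3 alone.

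In total, camera called 14 of 39 lists, 3 higher and 11 lower. With an estimated correlation it called 0, with 3 at an unadjusted p under 0.05, the lipid-associated macrophage, cholesterol synthesis and matrix lists. The self-contained test fry also called 0 for a one-way change, with 6 at an unadjusted p under 0.05, and 14 for changes in either direction. For 7 uncalled lists the median differed in sign from camera's direction, namely pan-macrophage, M1, M2, fatty acid synthesis, liver X receptor, pericyte and erythroid genes. The mean did so for 4, the M2, fatty acid synthesis, pericyte and enteric nerve lists.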

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

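Of the alternatives, leaving out vehicle 2 and vehicle 3 together, leaving out population outliers and the named-gene background were chosen after the results were seen. With camera at the preset correlation, 10 of the 14 called lists kept their calls whichever array was left out. The matrix, mesothelial and lipid-associated macrophage lists were among these. So were the B cell and T cell lists, although their medians on slide 2 were 0.25 and 0.56. Leaving out 1 array cannot show an effect shared by several arrays. The 24 genes with the largest differences never turned sign. Against 215 changed genes (186 higher, 29 lower) and 1285 at least 2-fold with an unadjusted p under 0.05, normexp gave 669 of the latter. Without a filter 106 changed (98 higher, 8 lower), and the trended robust variance gave 46 lower. Array weights, at 8.28 for vehicle 1 and 0.292 for propolis 3, gave 3231 (1674 higher, 1557 lower; 2087 at least 2-fold), of which 51.8% were higher against 86.5%. A block on replicate number gave 73 (65 higher, 8 lower). Deviations from the group mean correlated at 0.036, 0.291 and 0.135 between vehicle and propolis arrays of the same number. Between arrays of different numbers they correlated at -0.31 to 0.206. So few arrays cannot tell whether the numbers pair samples. The slide block gave 57 lower, and slide 1 alone 0 (0 higher, 0 lower) with limma, 5856 at an unadjusted p under 0.05 and 2271 of these at least 2-fold. Without vehicle 1, 2 or 3 in turn 53 (43 higher, 10 lower), 11 (11 higher, 0 lower) and 41 (38 higher, 3 lower) changed. Without propolis 1, 2 or 3 it was 77 (75 higher, 2 lower; 1190 at least 2-fold with an unadjusted p under 0.05), 11 (11 higher, 0 lower) and 94 (72 higher, 22 lower; 2023 at least 2-fold). An adjusted p under 0.1 gave 526 (423 higher, 103 lower). Without vehicle 2 and vehicle 3 together limma called 0 (0 higher, 0 lower), with 1362 at an unadjusted p under 0.05, taking the lone vehicle array to vary as propolis arrays do. Against 14 called lists, an estimated correlation gave 0 and fry 0, with 3 and 6 at an unadjusted p under 0.05. Intestinal genes turned from -1.76 to 1.89 on slide 1 alone (adjusted p = 0.00123) and to 1.33 without vehicle 2 and vehicle 3 (adjusted p = 0.0117), and acinar genes went from -2.67 to -0.22 (adjusted p = 0.953) there. Leaving out saturated probes was not run because no spot was saturated.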

Other observations

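The genes in this part and the tests of the patterns were chosen after the results were seen, except the test on skeletal muscle genes, whose prediction was written before its values were looked at. The genes first named here were not refitted with an array left out. A list of tendon and ligament genes was drawn up after Scx and Tnmd were seen among the genes that rose, and holds both, so no p is given for it. Of 10 measured, 9 were higher, with a median of 2.76. Scx, Tnmd and Kera, a corneal and tendon proteoglycan gene, rose, and Fmod (2.26, adjusted p = 0.0751), Thbs4 (3.12, adjusted p = 0.105) and Prg4 (2.39, adjusted p = 0.111) did not pass. The list averaged -2.46 to -2.11 in vehicle and -0.14 to 0.59 in propolis.

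Among the 186 genes that rose, 4 picked here act in WNT signalling, and no list of WNT, growth factor or complement genes was tested. The ligand gene Wnt4 was 14.2-fold higher (adjusted p = 0.00652), the secreted modulator genes Sfrp1 5.17-fold (adjusted p = 0.0153) and Sfrp2 6.83-fold (adjusted p = 0.0396), and the receptor gene Fzd1 by 1.58 (adjusted p = 0.0307). Of genes for growth factors, those picked were Mdk, encoding midkine, higher 9.53-fold (adjusted p = 0.00652), Nrg1 8.22-fold (adjusted p = 0.0153), Ntf5, a neurotrophin gene, 7.97-fold (adjusted p = 0.0172) and Tgfb3 by 2.05 (adjusted p = 0.0464). The complement gene Cfb (3.50-fold, adjusted p = 0.0320) rose, as did Clu, encoding clusterin, 6.18-fold (adjusted p = 0.0172). Star, a steroid synthesis gene, was 5.33-fold higher (adjusted p = 0.0172), and Cyp26a1, which encodes a retinoic acid hydroxylase, at least 9.76-fold (adjusted p = 0.0172). Ffar4, a fatty acid receptor gene, fell by 1.47 (adjusted p = 0.0488), while Dcstamp, a cell fusion gene of macrophages and osteoclasts, differed by -3.38 without passing (adjusted p = 0.0518).

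The 186 genes that rose could reflect a larger share of mesothelial cells, pieces of muscle with tendon, or the scaling. Of them 33.3% (62) rose by more, less 1 SE, than the mesothelial median of 1.46 plus 1 SD of 1.00. This leaves a larger mesothelial share open. Of the 186, 17 rose by more, less 2 SE, than the mesothelial marker that rose most plus its SE of 0.351. These 17 are picked by the size of their rise, so they exclude nothing. Skeletal muscle genes had a median of -0.15 (SD 0.556), which speaks against muscle pieces. Under quantile scaling 87.4% of calls were higher, against 86.5% under the main processing, which speaks against the percentile scaling. A percentile over detected probes gave 83.7% and normexp background correction 84.4%. The former is again a percentile scaling and the latter alters the background correction, so neither can decide about the scaling. Of the 10 ways to split the 6 arrays into 3 and 3, 1 gave as many genes, the real one with 215, and the highest other gave 0 with limma, with up to 2729 at an unadjusted p under 0.05. For lists 4 of 10 splits gave at least the real 14, the real one among them. Every other split called lists too, from 6 to 22, so the real list count did not stand out. With 10 splits, neither the gene count nor the list count can be settled. Whether such high counts come from structure among the samples or from the preset correlation was not tested.

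The lower lipid-associated macrophage genes Mmp12, Lgals3 and Itgax could come from fewer macrophages, or from tissue carried over in 1 vehicle array. Pan-macrophage genes had a median of -0.0891 (SD 0.420) against -0.83 for the lipid-associated list, which does not favour a smaller macrophage share. With 1 vehicle array left out the list's median nearest to 0 was -0.73, which does not favour tissue carried over in 1 vehicle array alone. Leaving out 1 array cannot show material shared by several vehicle arrays. Medians of the adipocyte, blood endothelial and dendritic lists were lower too, at -0.71, -0.80 and -0.58. Which cells the lipid-associated genes came from was not tested. A change of state within macrophages remains possible and was not tested.

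The lower B cell genes Cr2 and Ms4a1 might come from lymphoid tissue in vehicle 1 and vehicle 2. Lymph node vessel and follicle genes, also a list drawn up after the results, had a median of -1.13. Their mean in the lower of those 2 arrays was 0.44 below the highest of the other 4 arrays (-0.44, SD 0.589), which leaves this open. Vehicle 3 had a B cell mean of -2.01, inside the propolis range of -2.80 to -1.71.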
